A study of Zea mays with 8 samples.

How the data were processed

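RNA-seq was performed on 8 libraries of endosperm from maize (Zea mays) of the inbred line A188, collected 19 days after pollination and enriched for the EAS, the endosperm adjacent to the scutellum. Per the labels, 4 libraries came from wild type kernels and 4 from a KIL1 KIL2 knockout. KIL1 and KIL2 are NAC-family transcription factors. The labels do not say whether the libraries of a group came from separate plants, ears or pools, so p-values measure only the spread between these samples, which may be technical in part.

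Per the labels' protocols, total RNA was purified in 2 steps with DNase treatment, and paired-end libraries were sequenced on an Element AVITI instrument. Per the submitters' processing notes, Trimmomatic 0.39 and HISAT2 were used, and the version of HISAT2 is not given in the sources used here. Per the file headers, the authors deposited raw read counts per gene from featureCounts 2.0.1 with an A188 annotation. Per the file headers, no option for strand, pairs, multi-mapping reads or overlapping genes was set. The counts therefore ignored strand, left out reads with several alignments or several genes, and counted the reads of a pair separately. Set against the number of read pairs the labels state for the run, the counts came to 1.4 per pair, or 70.2% of the single reads, which also shows that reads and not pairs were counted. Counts of near-identical gene copies are uncertain, because reads aligning to several copies were not counted. Reads of genes with exon overlap on the opposite strand (922 of the tested genes, 4.2%) could not be assigned by strand.

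The deposited table held 37965 gene IDs, with 37778 genes on 10 chromosomes, 55 plastid genes, 12 mitochondrial genes and 120 genes on other sequences. The table gave each gene's exon coordinates and summed exon length, here called exon length, since 46.1% of the lengths were multiples of 3 and the models mix coding and untranslated parts. The IDs are not paired with gene names in the table, and 0 of the 37965 IDs matched any identifier among the 49888 genes of the reference table used for names (B73 assembly Zm-B73-REFERENCE-NAM-5.0). Gene names, the gene lists planned by name, product families and the levels of KIL1 and KIL2 were therefore not analysed here. In their place, groups were taken from the table itself (chromosome, organelle, exon number, exon length, mean expression, form of the ID). These groups were fixed after the layout of the table was seen and before any test between the genotypes. Coordinates are those of the deposited A188 annotation.

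Totals ranged from 47143888 to 80577963 counts per library. Tests used R 4.3.3 and edgeR 4.0.16. Genes were kept by edgeR's filterByExpr, which left 22014 genes holding 99.96% of all counts. Libraries were scaled by TMM factors, and genes were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), knockout against wild type, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The test, the design without a replicate block, the thresholds and most of the alternatives named below were fixed before the data were examined. Standard errors of log2 fold changes were derived from the F statistic. CPM values are normalised counts, scaled by the TMM-adjusted library size. Groups were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry (limma 3.58.1). Shares of counts were compared with exact permutation tests, two-sided, whose smallest p with 4 libraries against 4 is 0.0286. Chromosome positions were tested in windows of 50 consecutive tested genes (hypergeometric test, adjusted over windows), and neighbouring genes were compared with 1000 shuffles of the calls over positions. For a gene without a count in one group, the fold bound was computed against 3 counts over that group. These bounds allow for counting error in the group without a count only. They leave out counting error in the other group and the spread between libraries.

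The rule for genes named in the text was the largest changes in each direction among genes with an adjusted p below 0.05, a mean log2 CPM of at least 1 and no overlap between the libraries of the groups, 12 per direction. Since the IDs carry no names, 2 of each 12 are given by ID and the others as ranges. Regions given by position were chosen after their values were seen, except the stretches of abundant genes, which are all that met a rule of at least 2 of the 100 most abundant genes less than 1 Mb apart. That rule, the share of counts in the 100 most abundant genes and the comparison of neighbouring genes were set after a first look at the changed genes.

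The procedure was tested on simulated data made from the means, dispersions and library sizes of the knockout against wild type comparison. Among 21780 genes that passed the filter there, edgeR recovered 44.6% of genes changed 1.5-fold, 81.5% of genes changed 2-fold and 93.8% of genes changed 4-fold, with 11 false calls among 153. Only 65, 65 and 64 genes were changed at these folds, while 4086 were called in the data. The adjusted threshold was therefore stricter in the simulation, and these shares do not give the recovery in the data. Replicate pairs were checked for repeated libraries. The chi-square statistic per degree of freedom lay between 10.89 and 36.48 for all 12 pairs within groups, so no libraries agreed within sampling noise. Alternatives were other scalings (relative log expression, upper quartile, library totals), no count filter, a stricter filter (10 counts in 4 libraries and a mean of 1 CPM), DESeq2 1.42.0, limma-voom, a replicate block, halved counts and leaving out each library.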

Results

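To examine what the loss of KIL1 and KIL2 does to the endosperm next to the embryo, transcript levels were compared between EAS-enriched endosperm of a KIL1 KIL2 knockout (4 libraries) and of wild type maize of the line A188 (4 libraries), 19 days after pollination. Knockout libraries held 47143888 to 65625013 counts and wild type libraries 58330218 to 80577963 counts. A count was recorded for 25798 to 26949 genes per knockout library and for 26536 to 27592 genes per wild type library. The first principal component of log2 CPM held 41.1% of the variance and separated the genotypes. The second held 16.7% and set knockout replicate 1 apart from the other knockout libraries. Spearman correlations across genes were 0.9919 to 0.9954 within the knockout, 0.9943 to 0.9957 within wild type and 0.9843 to 0.9905 between the groups. KIL1 and KIL2 transcripts themselves were not analysed here, so the genotype labels were not checked against the targeted genes.

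**Figure D1:**
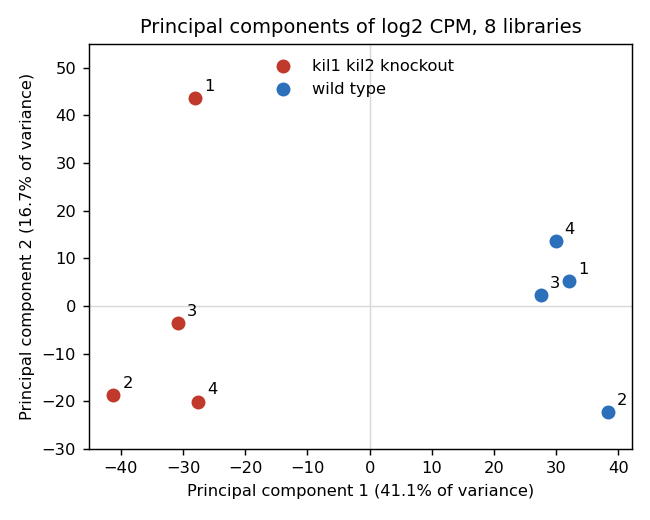
Principal components 1 and 2 of log2 CPM over the tested genes, 1 point per library, numbered by replicate. Component 1 (41.1% of the variance) separates the 4 knockout from the 4 wild type libraries, and knockout replicate 1 has the highest value on component 2, 43.7.

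Transcript levels differed widely between the knockout and wild type libraries, mostly by small amounts. Of 22014 genes tested, 4086 (18.6%) changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), of which 1873 rose and 2213 fell. The median change was 1.32-fold among genes that rose and 1.4-fold among genes that fell, and 3400 of the changed genes (83.2%) changed by less than 2-fold. A change of at least 2-fold was found for 686 genes (304 higher and 382 lower), and for 380 (158 higher and 222 lower) with the stricter count filter, which removes genes of low expression. The balance of these rises and falls turned without knockout replicate 1 (389 higher and 353 lower) and without wild type replicate 2 (285 higher and 271 lower), and falls outnumbered rises without each of the other 6 libraries. With the first filter, 128 genes changed at least 4-fold (67 higher and 61 lower) and 29 genes changed at least 8-fold (18 higher and 11 lower). The libraries of the 2 genotypes did not overlap for 3744 of the 4086 changed genes. Over all tested genes this held for 23.2%, where chance gives 2.86% with 4 libraries against 4. The split between rising and falling genes depended on scaling: with library totals in place of TMM factors, an alternative chosen after seeing the data, the median log2 fold change of all genes moved from -0.003 to -0.12, and 1032 genes rose while 4743 fell. Upper quartile factors turned the balance the other way, with 2229 genes that rose and 2000 that fell at a median of 0.017.

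**Figure D2:**
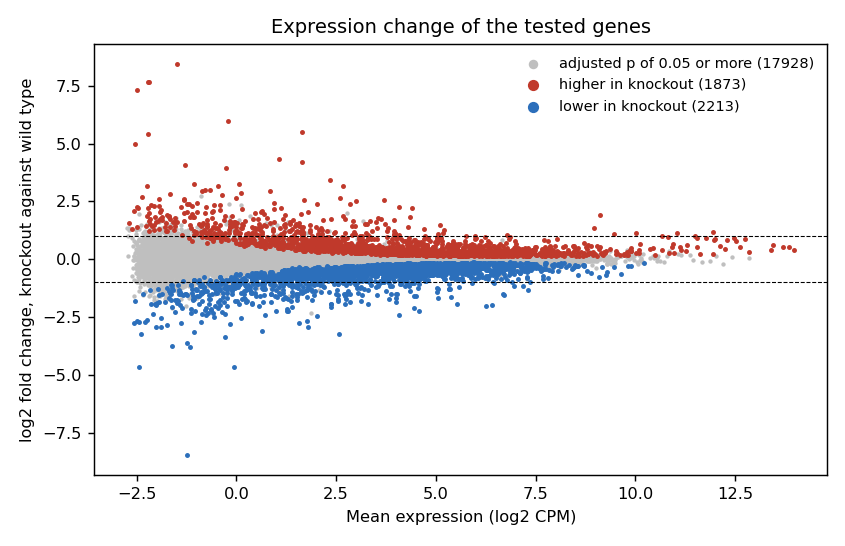
Log2 fold change, knockout against wild type, against mean expression in log2 CPM for the 22014 tested genes, with genes past the threshold in colour and dashed lines at 2-fold. Of the 100 genes with the highest expression 52 rose and 4 fell, while 1873 rose and 2213 fell over all tested genes.

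The largest rises exceeded the largest falls among genes with a mean log2 CPM of at least 1. The gene Zm00001d045654 (chromosome 9, 160967406 to 160969115, 2 exons) measured 6.17 ± 2.10 CPM (SD, n = 4) in the knockout and 0.128 ± 0.095 CPM in wild type, a 45.3-fold rise (log2 fold change 5.50, SE 0.42, edgeR adjusted p = 3.87e-05). Its wild type level rested on 2 to 20 counts per library. The gene Zm00001d037944 (chromosome 5, 94392634 to 94394501, 8 exons) measured 4.08 ± 0.51 CPM in the knockout and 0.198 ± 0.022 CPM in wild type, a 20.4-fold rise (log2 fold change 4.35, SE 0.18, edgeR adjusted p = 5.01e-07). In the other direction, gene:Zm00001d052433 (chromosome 4, 198105040 to 198106553, 2 exons) measured 1.10 ± 0.65 CPM in the knockout and 10.4 ± 1.95 CPM in wild type, 9.29-fold lower (log2 fold change -3.22, SE 0.37, edgeR adjusted p = 0.000256). The gene Zm00001d053263 (chromosome 4, 204537396 to 204540534, 8 exons) measured 0.784 ± 0.229 CPM in the knockout and 5.97 ± 0.73 CPM in wild type, 7.51-fold lower (log2 fold change -2.91, SE 0.19, edgeR adjusted p = 1.94e-05). The 12 largest rises ranged from 4.17-fold to 45.3-fold and lay on 8 chromosomes. The 12 largest falls ranged from 4.32-fold to 9.29-fold and lay on 7 chromosomes. The ID numbers of Zm00001d045654, Zm00001d037944 and Zm00001d053263 are out of order for their positions, a class of genes taken up under Other observations.

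**Figure D3:**
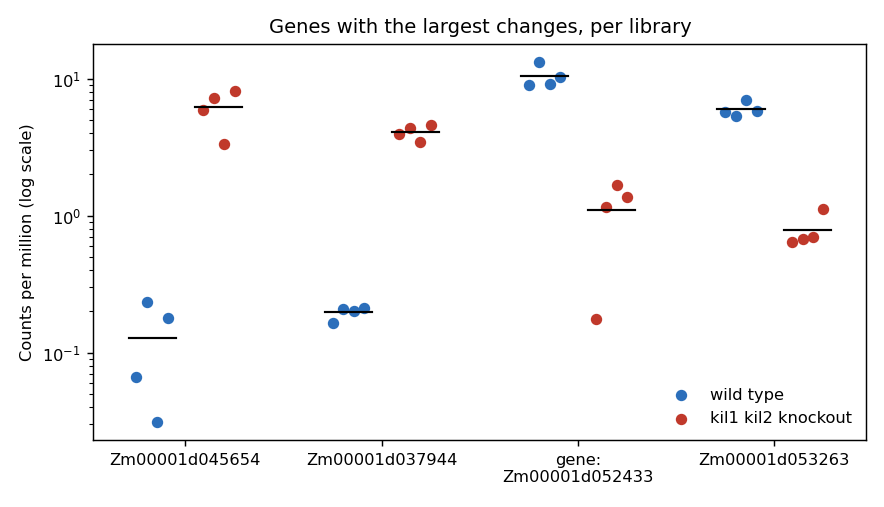
CPM on a log scale for the 2 genes with the largest rise and the 2 with the largest fall, 1 point per library and a line at the mean of the 4 libraries. The rule by which these genes were chosen required that the libraries of the 2 genotypes not overlap. For Zm00001d045654 knockout levels were 3.35 to 8.17 CPM against 0.031 to 0.233 CPM in wild type.

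Among tested genes, 5 had no count in any library of one genotype. Of these, 4 were counted in the knockout and in no wild type library. They lay on chromosome 7 (99721184 to 99723070, 155 counts in the knockout), chromosome 4 (87586744 to 87587743, 89 counts), chromosome 9 (1812206 to 1813138, 88 counts) and chromosome 8 (73001681 to 73002956, 70 counts). Against a limit of 3 counts over the wild type libraries, the counts seen in the knockout were 63.6-fold, 36.5-fold, 36.1-fold and 28.7-fold higher, in that order. No allowance was made for counting error in the knockout counts. The fifth, on chromosome 9 (69749824 to 69750588), had 197 counts in wild type and none in the knockout. It was 53.4-fold lower against the same limit, set here on the knockout. Each of the 5 passed the edgeR test, with the largest adjusted p at 0.001. This is no added support. A gene without a count in one genotype passed the count filter only if all 4 libraries of the other held counts, here at least 12 each.

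Among the most abundant transcripts of the tissue, rises outnumbered falls in the knockout. Of the 10 most abundant genes 9 rose and 0 fell, of the next 90 genes 43 rose and 4 fell, of the following 900 genes 139 rose and 68 fell, and of the remaining 21014 genes 1682 rose and 2141 fell. The 100 most abundant genes took 29.5% ± 1.27 of all counts in the knockout (SD, n = 4) and 24.1% ± 0.84 in wild type. The shares were 28.5% to 31.3% in the knockout libraries and 23.1% to 24.9% in the wild type libraries (exact permutation test, two-sided, p = 0.0286, the smallest 4 against 4 can give). Adjusted over the 7 library measures compared, this p was 0.0667, which misses 0.05. The genes with a larger relative change in this set included one on chromosome 1 (165830827 to 165831549), at 5544 ± 749 CPM in the knockout and 2416.5 ± 455 CPM in wild type, and one on chromosome 2 (236297623 to 236300006), which fell from 976 ± 162 CPM to 624 ± 98.5 CPM. As a set, the 100 genes passed camera at its preset correlation (edgeR fit, adjusted p = 2.24e-19). The call was lost by camera with an estimated correlation (adjusted p = 0.352), which was 0.212 for this set against the preset 0.01. The test fry gave an adjusted p of 0.007. The median log2 fold change of the set was 0.21 with TMM factors and stayed above 0 under each of the other 3 scalings (0.213, 0.231 and 0.094).

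Stretches with at least 2 of the 100 most abundant genes less than 1 Mb apart numbered 3, and the largest was a cluster on chromosome 4 between 5312944 and 5775900. It held 11 of the 100 most abundant genes, each with 702 to 804 bases of exon and 10 of them with a single exon. Of these 11 genes 10 rose and 0 fell, and the ratio of knockout to wild type was 1.28-fold to 2-fold over all 11, the one below the threshold (edgeR adjusted p = 0.099) included. Together they took 5.98% ± 0.56 of all counts in the knockout and 4.07% ± 0.44 in wild type. Of the other 12 tested genes of the interval 0 rose and 1 fell. Over chromosome 4 as a whole 9% of the tested genes rose, so 12 genes are too few to set these apart. A pair of abundant genes on chromosome 7 (19890675 to 19899209) rose 1.52-fold and 1.81-fold and took 2.14% ± 0.15 of counts against 1.43% ± 0.18. Another pair on chromosome 7 (123273645 to 123302389) rose 1.33-fold and 1.91-fold and took 2.22% ± 0.2 against 1.7% ± 0.1. The exact permutation p of the share was 0.0286 for each of the 3 stretches, before and after adjustment over them (two-sided, 4 libraries against 4), and is not independent evidence, since the stretches were drawn from a set already seen to differ. If these neighbours are near-identical copies, their counts depend on which reads aligned to a single place.

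**Figure D4:**
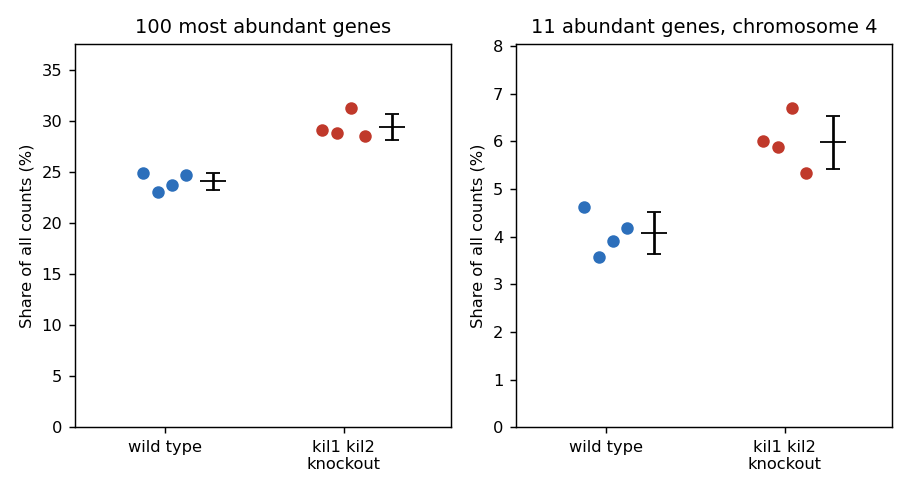
Share of all counts, in percent, taken by the 100 most abundant genes and by the 11 of them that lie between 5312944 and 5775900 on chromosome 4, 1 point per library with the mean and SD of the 4 libraries beside it. The knockout libraries lie above the wild type libraries in both panels, at 29.5% against 24.1% and at 5.98% against 4.07%.

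Changed genes were spread over all 10 chromosomes. Between 7.7% and 9% of the tested genes of a chromosome rose and between 8.2% and 11.3% fell, and no chromosome stood apart in camera (edgeR fit, adjusted p = 0.989 or higher). Of 435 windows of 50 consecutive tested genes, 0 passed the adjusted threshold (hypergeometric test, smallest adjusted p = 0.624), and 24 had an unadjusted p below 0.05. For changes of at least 2-fold 0 windows passed as well (smallest adjusted p = 0.376), and 11 had an unadjusted p below 0.05. On a shorter scale neighbouring genes changed alike: 480 adjacent pairs of tested genes changed in the same direction, against a mean of 382.3 and a highest value of 442 over 1000 shuffles of the calls (one-sided permutation p = 0.001, the smallest the shuffles can give). For changes of at least 2-fold there were 35 such pairs against a mean of 10.9. The rank correlation of neighbours' log2 fold changes across genes was 0.046. It was 0.017 to 0.042 in the 18 other splits of the 8 libraries that put 2 libraries of each genotype on either side. Of the other splits, which put 3 libraries of one genotype on a side, 2 gave higher values than the real one, 0.0494 and 0.0475.

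The 35 pairs made up 31 regions with 66 genes, 12 regions higher and 19 lower in the knockout. On chromosome 5 (94392634 to 94396610) 2 genes set 561 bases apart rose 20.4-fold and 18.5-fold and were counted 2235 times in the knockout and 143 times in wild type. On chromosome 3 (156161573 to 156169102) 2 genes, one inside the span of the other without shared exons, rose 8.87-fold and 9.01-fold, on 368 counts in the knockout and 49 in wild type. On chromosome 4 (204530072 to 204540534) 3 adjacent genes fell between 4.72-fold and 25.4-fold and were counted 370 times in the knockout and 3101 times in wild type. These 3 regions were chosen after their values were seen, and the counts do not tell strands apart. The genes of the chromosome 5 region (Zm00001d037944 and Zm00001d009275) carry ID numbers out of order for their positions. So do Zm00001d053263 and Zm00001d050962 in the chromosome 4 region.

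**Figure D5:**
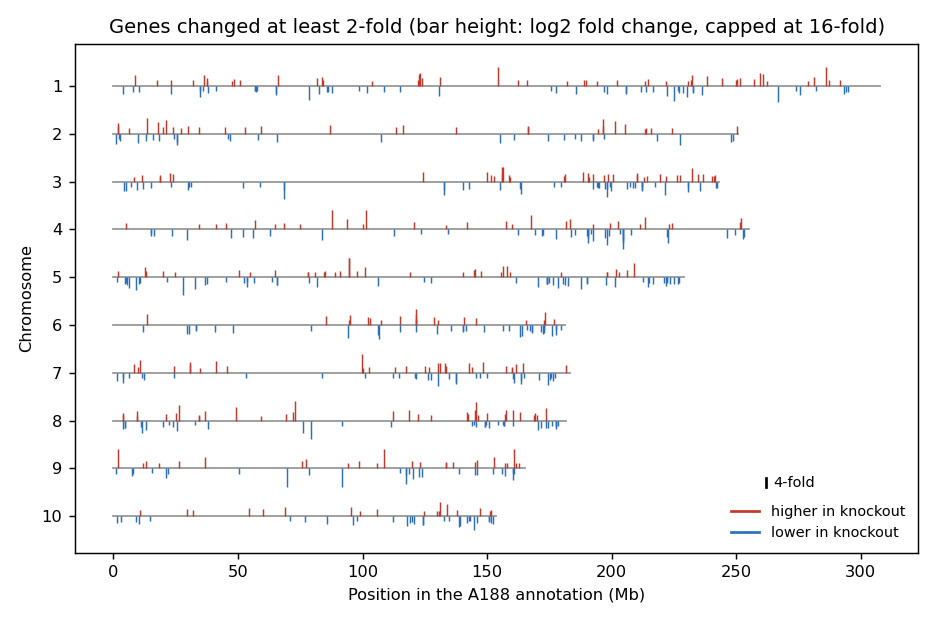
Positions in Mb, in the deposited A188 annotation, of the genes changed at least 2-fold on the 10 chromosomes, with bars up for genes higher and bars down for genes lower in the knockout and bar height in proportion to log2 fold change, capped at 16-fold. Rises and falls, 304 and 382 over all sequences of the annotation, lie on each of the 10 chromosomes.

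Genes that fell and genes that rose differed in exon length, a difference not tested by itself. Genes that fell had a median exon length of 2144 bases, genes that rose 1795 bases, and tested genes not past the threshold 1833 bases. Single-exon genes made up 16.7% of the genes that rose and 13.6% of those that fell. In the quartile of shortest genes 480 rose and 373 fell, and in the quartile of longest genes 396 rose and 606 fell. Neither quartile passed camera (edgeR fit, adjusted p = 0.989), and of the length quartiles only the third passed fry, in the lower direction (adjusted p = 0.000742). The third quartile did not pass camera at the preset correlation (adjusted p = 0.989) or an estimated one (adjusted p = 0.352), and its median log2 fold change was -0.013. Of 3552 single-exon genes tested 313 rose and 301 fell, and of 5339 genes whose ID carries the prefix gene: 556 rose and 602 fell. Counts of organelle genes were few, with 185 to 310 plastid counts and 50 to 103 mitochondrial counts per library. Reads with several alignments were left out, so these counts do not give the level of organelle transcripts. Of the 5 plastid and 2 mitochondrial genes tested by edgeR 0 passed the adjusted threshold and 0 had an unadjusted p below 0.05, and both counts were 0 with DESeq2 and limma-voom as well.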

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

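Values per library were searched for samples far from the rest of their group of 4 in 26 sets of values, of which 3 had one; chance alone gives about 1 in 20. Wild type replicate 2 held 80577963 counts, where the other wild type libraries held 58330218 to 61613873. Knockout replicate 3 had 12.3% of its counts in the 10 most abundant genes, where the other knockout libraries had 10.82% to 10.96%. Knockout replicate 4 had 1.12 CPM of Zm00001d053263, where the other knockout libraries had 0.638 to 0.7 CPM, and the fall of this gene was -3.15 on the log2 scale without that library and -2.91 with it.

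The number of changed genes was compared with that in other splits of the libraries. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many as 4086 changed genes, the real one, and the highest of the others was 0. For changes of at least 2-fold 1 split gave as many as 686, again the real one, with 0 as the highest other. The other splits mix the genotypes, so a difference between the genotypes adds to the spread within their groups and lowers their calls. The comparison also cannot tell genotype from any other difference shared by the libraries of a group. For the groups of genes taken from the table, chance was not excluded: 34 of the 35 splits passed at least as many groups by camera as the real split (1), and the highest other passed 6.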

How the results depend on the processing

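Library totals, halved counts and the alternative settings for the groups, the neighbours and the share of abundant genes were chosen after the data were seen. The count of changed genes stayed within 1.5 times 4086 in all 17 alternatives, from 2783 to 5775, and 0 of the 4086 genes turned direction in any of them that tested the gene. It was 4874 with DESeq2, 4074 with limma-voom, 4108 with relative log expression, 4229 with upper quartile factors, 5775 with library totals, 3932 without a count filter, 3883 with the stricter filter and 4121 with halved counts. Leaving out each library gave 2783 (without wild type replicate 2) to 4012 changed genes and 556 to 742 genes changed at least 2-fold, of which 255 to 389 were higher and 271 to 457 lower. The stricter filter moved the count of genes changed at least 2-fold from 686 to 380 (158 higher and 222 lower), since it removes genes of low expression and left 18101 genes to test. Library totals changed the split to 1032 rising and 4743 falling genes. With the replicate number as a block the counts were 3000 and 602. Samples with the same number did not clearly deviate together (correlations of 0.1, 0.1, -0.05 and -0.13). Of the 8 libraries, 2 correlated best with their own number in the other group. These values cannot tell whether samples with the same number share an ear, plant or day, which the labels do not say.

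The 4 genes given by ID kept their direction and their adjusted p below 0.05 in all 17 alternatives. The number of groups past the threshold was 1, 0 with an estimated correlation and 2 with fry. For the 100 most abundant genes the estimated correlation was 0.212, against the preset 0.01, and camera's call on them was lost at the estimated value. Why fry passed another group was not tested. The difference in the share of the 100 most abundant genes was 5.34 percentage points and lay between 4.72 and 5.65 when each library was left out, 2.57 for the 10 most abundant genes and 4.21 for the 1000 most abundant. The ratio of neighbouring pairs changed alike to shuffled positions lay between 1.23 and 1.39 without each library, and was 3.22 for changes of at least 2-fold. No window of genes passed under either threshold. Alternatives planned for gene lists, product families and KIL1 and KIL2 were not run, since the IDs matched no names. With halved counts 20568 genes were left to test, against 22014, and 608 changed at least 2-fold, against 686. In simulated data at the depth of these libraries, but with far fewer changed genes than were called here, 44.6% of genes changed 1.5-fold were recovered.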

Other observations

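The tests of library size, a few abundant genes, tissue mix, overlapping gene models, neighbours without the knockout, a segment from another line and expression level below were chosen after the result was seen, and the patterns themselves were noticed in the data. The knockout libraries differed more from each other than the wild type libraries did: the biological coefficient of variation over genes was 0.125 in the knockout and 0.101 in wild type. Without knockout replicate 3 it was 0.108, and without each of the other knockout libraries it was 0.128 to 0.135. The difference was not tested.

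The table holds another group of genes with large changes. IDs run in order along the A188 chromosomes, except for 5245 of 37765 genes whose ID number lies more than 200 from the median of the 10 neighbours on each side. Of the 1079 such genes tested 126 changed (11.68%, against 18.95% of the genes in sequence), but 23 changed at least 4-fold (2.13% against 0.5%), 18 of them higher and 5 lower in the knockout. The odds ratio for a 4-fold change was 4.31 (95% interval 2.61 to 6.85, Fisher's exact test across genes, which are not independent replicates, p = 6.22e-08). Of the 5 genes without a count in one genotype 3 were out of sequence. Among the genes given by ID, Zm00001d045654 lies between Zm00001d048333 and Zm00001d048424 on chromosome 9. On chromosome 4, Zm00001d053263 lies between gene:Zm00001d052433 and Zm00001d052946, and on chromosome 5, Zm00001d037944 lies between gene:Zm00001d015376 and gene:Zm00001d016198. By their ID numbers these genes belong to the out-of-sequence class, so the untested hypotheses given below apply to them too.

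Low expression alone does not account for this excess, although out-of-sequence genes had a median log2 CPM of 0.69 against 3.54. Within deciles of mean expression the odds ratio was 2.08 (95% interval 1.31 to 3.28), and 1.93 to 2.1 with other distances or numbers of neighbours. A few linked segments did not hold most of these genes, since 21.7% of the 23 lay within 5 Mb of another of them, on 9 chromosomes in all. Random draws of out-of-sequence genes gave a mean of 12.9% (permutation p = 0.169), so clustering of a part of them is neither shown nor excluded. A remaining hypothesis is that such genes may differ in copy or position between the plants of the 2 genotypes, or share reads with copies elsewhere. Neither was tested, because sequence was not used here.

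The larger share of counts in the most abundant genes is not accounted for by library size: among the 5 libraries within 5% of the median total the 2 from the knockout had shares of 28.82% and 31.31% and the 3 from wild type 23.78% to 24.91%, a difference of 5.6 percentage points. Nor did it rest on the top 10 genes alone. With the counts of those genes removed, the next 90 took 20.5% ± 0.82 of the remaining counts in the knockout and 16.9% ± 0.53 in wild type. This difference of 3.61 points refers to the remaining counts and not to all counts. In the 18 splits with 2 libraries of each genotype on either side, the difference in the share of all counts in the 100 most abundant genes reached at most 1.48 points. Camera at its preset correlation called the most abundant genes in 6 of these splits and is no evidence here. A mix of tissues or a stage that differs with genotype cannot be told apart from an effect of the genotype within the same cells. Differences between libraries of a group followed the knockout change weakly (largest absolute r across genes 0.189 of 12 pairs), but a mix tied to genotype would leave no such trace.

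For neighbouring genes that changed alike, overlapping gene models are argued against, since pairs at least 10 kb apart still exceeded shuffled positions by a ratio of 1.19. Co-variation of neighbours without the knockout stays open: the rank correlation was 0.046 in the real split and at most 0.0417 in the 18 splits with 2 libraries of each genotype on either side, where 1 of 19, the real one included, is too few splits for a share below 0.05. Splits with 3 libraries of one genotype on a side reached 0.0494 and 0.0475, but hold part of the difference between the genotypes. A segment from another line linked to the knockout stays open, since 0 windows passed the threshold but a segment with few differing genes would not pass it.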
